A study of Danio rerio with 18 samples.

How the data were processed

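RNA was measured in lateral line primordium cells of zebrafish (Danio rerio) embryos on 18 Affymetrix zebrafish gene arrays, in 3 groups of 6 arrays. The lateral line primordium is a cluster of epithelial cells that migrates along the trunk and leaves behind sensory organs. Control embryos carried the cldnb:lynGFP and cxcr4b:nls-tdTomato transgenes and received 10 µM RU486 and 0.1% DMSO. SU5402 embryos had the same transgenes and carriers plus 1 µM SU5402, an inhibitor of FGF receptor 1. FGF overexpression embryos received the carriers alone and carried in addition the cxcr4b:LexPR driver, which RU486 switches on, and the lexOP:Fgf3-GFP transgene, so that the extra transgenes and Fgf3 cannot be separated. Per the labels' protocols, RNA was purified with a RNeasy Plus Mini kit and labelled with the Ambion WT Expression Kit. How the cells were isolated, with or without a sort, is not given in the sources used here.

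The deposited values are log2 signals, 1 per probe set and array. They were made with Affymetrix Power Tools by RMA, per the submitters' processing notes, which give no version. The values ran from 1.20 to 13.88 and were used as deposited, with no further normalization and no filter. All 75212 probe sets were tested. The files paired 20806 probe sets with 1 gene symbol each, 855 with several and 53551 with none, and the named ones covered 19260 genes. For the 1365 genes with more than 1 probe set, the probe set with the highest mean over the 18 arrays stood for the gene. The values of 14289 probe sets were identical to those of another probe set on every array, which left 65942 distinct sets of values. Of 757 symbols on the gene lists, 687 were found, 14 of them through an older symbol. Gene names and neighbouring genes were looked up in a table for the zebrafish assembly GRCz12tu. The build and annotation behind the array are not given in the sources used here. Positions in the GRCz12tu table gave the order of genes along the chromosomes, and no other coordinates were used.

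Each group comparison was a contrast in a single limma fit (limma 3.58.1, R 4.3.3) over all 18 arrays with 1 mean per group. The moderated two-sided test was adjusted by Benjamini-Hochberg over the 75212 probe sets, with a threshold of 0.05 and no minimum fold. Errors given as SE are the fit's standard errors of a log2 change. The number of arrays limits the precision. The fit was tested on simulated data with known changes. It recovered 34.3% of simulated log2 changes of size 0.5, 68.7% of size 1 and 95.5% of size 2 for SU5402 against control, over 75212 probe sets with 200 changed. For FGF overexpression against control the shares were 34.3%, 70.1% and 98.5%, and for FGF overexpression against SU5402, with 400 changed, 39.6%, 72.4% and 97.0%. False calls made up 7.04%, 1.46% and 3.47% of the calls. The simulations changed far fewer probe sets than passed in the data (7074, 3052 and 12731) and drew noise independently for each array. These shares therefore do not give the power of the real tests.

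The comparisons, their main tests, most alternatives, the rule for naming genes and the 29 gene lists were fixed before the data were examined. The measure and threshold for the relation between the effects of the 2 treatments, the tests of explanations and the tests of neighbouring genes and muscle markers were chosen or changed later. The 19 lists of pathways and states were FGF-ERK feedback and target genes, FGF ligands and receptors, immediate early genes, Wnt pathway and leading domain genes, Notch pathway genes, hair cell lineage genes, lateral line primordium identity genes, epithelial polarity, junction and apical constriction genes, basement membrane and matrix genes, BMP and TGF-beta pathway genes, cell cycle genes, ribosome biogenesis and MYC target genes, p53 target and apoptosis genes, heat shock genes, unfolded protein response genes, aryl hydrocarbon receptor and xenobiotic response genes, glycolysis and hypoxia genes, sterol biosynthesis genes, and steroid and glucocorticoid receptor response genes. The 10 lists of other cell types were skin and periderm, ionocytes, pronephros, skeletal muscle, neurons and glia, erythroid cells, leukocytes, endothelium, neural crest and pigment cells, and mesenchyme and cartilage. A list's shift was tested with camera at a preset correlation of 0.01, adjusted over the 29 lists within each comparison, with a correlation estimated for each list as an alternative.

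Named genes were, for each treatment against control, the 8 with the largest rise and the 8 with the largest fall among those past the threshold with all 6 treated arrays on the same side of the control mean. Symbols that are only clone or predicted-locus names were passed over. The FGF-ERK genes and fgf3 were named in all cases, with up to 4 members of each other list by smallest p. For FGF overexpression against SU5402 the 5 largest changes each way were named, and 10 genes with opposite effects. Single genes outside this rule were chosen after their values were seen and are described as such.

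The alternatives tried were a replicate block, a fit of the 2 groups compared only, a trended and robust variance, array weights, a repeated quantile normalization, a shift of array medians, a filter on dim probe sets, a minimum fold of 1.5, 1 probe set per gene, each array left out in turn, and fry and an estimated correlation for the lists. Identical sets of values counted once and the muscle marker level as a covariate were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. No column of the deposited table was left unused.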

Results

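Gene expression was measured on 18 arrays from zebrafish lateral line primordium cells, 6 from control embryos, 6 from embryos treated with the FGF receptor inhibitor SU5402 and 6 from embryos that overexpressed Fgf3 from a transgene. The comparisons ask how gene expression in these samples differs with less or more FGF signalling. Markers of other cell types were high on the arrays. The control mean was 10.69 (log2) for the skeletal muscle list and 9.31 for the skin and periderm list, against a median of 6.82 for named probe sets. Changes in cell composition therefore cannot be told apart from changes within primordium cells. Array medians lay between 5.89 and 5.99 (log2), and the correlation across probe sets between arrays of the same group lay between 0.967 and 0.983. The first principal component held 24.7% of the variance and separated all 3 groups, with scores of -75.0 to -56.6 for SU5402, -0.2 to 19.2 for control and 47.7 to 69.3 for FGF overexpression. The second held 11%, and on it replicate 6 lay below replicate 1 in each group. The scores were -63.9 against 22.5 in control, -31.4 against 21.5 in SU5402 and -11.8 against 47.5 in FGF overexpression.

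**Figure D1:**
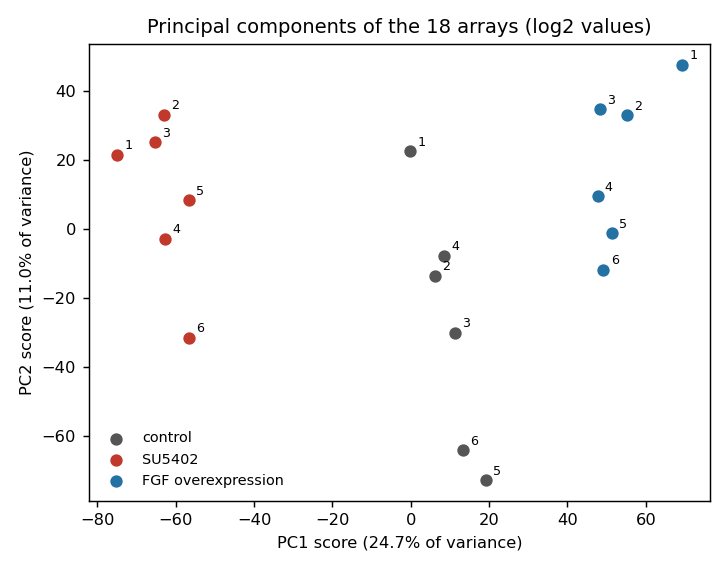
Scores of the 18 arrays on the first (horizontal) and second (vertical) principal components of the log2 values, 1 point per array, coloured by group and numbered by replicate. Control arrays lie between the SU5402 arrays (-75.0 to -56.6) and the FGF overexpression arrays (47.7 to 69.3) on the first component.

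The FGF ligand gene fgf3, which the transgene encodes, had a mean level of 7.12 (log2) in control, 9.11 in SU5402 and 12.38 in FGF overexpression. It was 38.5-fold higher under FGF overexpression (log2 change 5.26, SE 0.17, adjusted p = 1.64e-12, n = 6 per group) and 3.97-fold higher under SU5402 (log2 change 1.99, SE 0.17, adjusted p = 2.42e-07). Its level under FGF overexpression lay within 2 log2 units of the highest array value of 13.88, where an array can compress changes, and the true rise is not bounded above by these values. The files do not say whether its probe set reads the transgene as well as the native gene. The genes whose promoters drive the reporters did not pass the test in either comparison. For cxcr4b the log2 changes were 0.20 under SU5402 and 0.36 under FGF overexpression (adjusted p = 0.483 and 0.195), and for cldnb they were -0.07 and 0.03 (adjusted p = 0.656 and 0.880).

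Under SU5402 the FGF target gene etv4 and most measured cell cycle genes were lower, and the Wnt feedback gene notum1a was higher. Of 32 measured cell cycle genes 27 fell and none rose (camera adjusted p = 2.73e-29, and adjusted p = 0.00575 with an estimated correlation). The ETS transcription factor gene etv4, a target of FGF-ERK signalling, fell at least 11.5-fold (log2 change -3.53, SE 0.14, adjusted p = 1.34e-11, n = 6 per group). Folds are given as at least where the lower group's mean was at or below the median level of all probe sets (5.94 in SU5402, etv4 at 5.73), and log2 changes against such a group are measured values and lower bounds in size. The gene for the Wnt-inactivating enzyme Notum, notum1a, rose 11.6-fold (log2 change 3.54, SE 0.15, adjusted p = 1.94e-11). Skin and periderm markers were also lower on these arrays, with 13 of 28 measured members below control and 1 above (camera adjusted p = 1.87e-10, and adjusted p = 0.132 with an estimated correlation).

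In the limma test 7074 of 75212 probe sets passed (9.41%), 3526 higher and 3548 lower, whereas 2765 of 6787 were higher after a shift of array medians. By the 1 probe set that stood for each gene, 2832 of 19260 named genes passed, 1266 higher and 1566 lower, and 402 of the genes changed by at least 2-fold, 148 up and 254 down. Falls were largest for negaly6 (at least 27.8-fold, log2 change -4.80, SE 0.16), TMPRSS5, a transmembrane serine protease gene (-4.30, SE 0.20), the homeobox gene six2a (-3.84, SE 0.20), etv4, the fucosyltransferase gene fut9b.3 (-3.44, SE 0.25) and the galactosyltransferase gene b3galt10.1 (-3.35, SE 0.24). These 6 were at or below the median level in SU5402, so that their falls have no settled order. Then came sostdc1b, of a family of secreted BMP and Wnt antagonists (-3.23, SE 0.16) and the keratin gene krt1-c5 (-3.17, SE 0.16). The largest measured rise was 15.6-fold for adcyap1b, which encodes a PACAP neuropeptide (log2 change 3.97, SE 0.14). Next came notum1a, the EGF family ligand gene hbegfb (3.12, SE 0.13), the transcription factor gene osr1 (3.01, SE 0.12), OTOG, which encodes otogelin (2.96, SE 0.10), the transcription factor gene runx2a (2.86, SE 0.14), the calcium channel gene cacna1ba (2.75, SE 0.10, a lower bound) and the ligand gene wnt10a (2.67, SE 0.12). Adjusted p-values of these 16 genes ranged from 4.17e-12 for negaly6 to 2.01e-08 for b3galt10.1.

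Of 19 measured FGF-ERK feedback and target genes, 8 fell and 1 rose under SU5402. Adjusted over the list alone, 10 fell and 2 rose. The median log2 change was -0.29, and the list was lower than other genes (camera adjusted p = 0.000197), with adjusted p = 0.132 with an estimated correlation. After etv4, the falls were -1.52 for etv5b (SE 0.14), -0.85 for spred2b, -0.82 for spry4, -0.75 for etv5a, -0.75 for spry2, -0.58 for spred2a and -0.27 for spred1. Sprouty and Spred proteins are feedback inhibitors of the ERK pathway. The membrane protein gene flrt3 rose (2.15, SE 0.10). The ERK phosphatase gene dusp6 was at 0.03 (SE 0.11, adjusted p = 0.916). The other members that did not pass were spry1 (-0.41), il17rd (0.22), dusp4 (-0.29), cdc42ep3 (-0.36), dusp2 (-0.20), dusp5 (-0.18), spred3 (-0.09), etv1 (-0.09) and dusp1 (0.06). The call for spred1 was lost when only the SU5402 and control arrays were fitted (adjusted p = 0.0582), and its other probe set did not pass. With array weights and after a shift of array medians spry1 passed (adjusted p = 0.0369 and 0.0388), and with a trended and robust variance il17rd did (adjusted p = 0.0285).

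**Figure D2:**
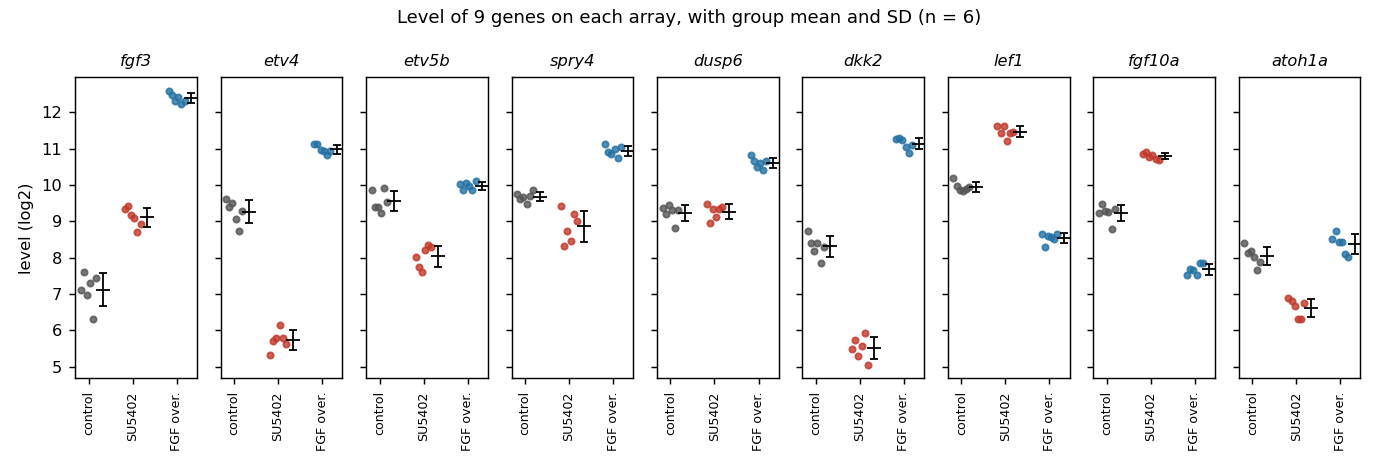
Level (log2, vertical) of 9 genes on each array, by group (horizontal), with 1 point per array and the group mean and SD (n = 6) beside the points. For dkk2 the SU5402 arrays lie below control by 2.81 in the mean and the FGF overexpression arrays above it by 2.82, whereas dusp6 differs from control by 0.03 under SU5402 and 1.37 under FGF overexpression.

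Among FGF ligands and receptors, 5 of 19 rose and 3 fell under SU5402, the same counts as when adjusted over the list alone. The ligand genes fgf10b (2.40) and fgf10a (1.56) rose with fgf3, and the receptor gene fgfr1a fell (-1.26). The list's median was -0.04 and its mean 0.15, opposite in sign, and the test pointed up without passing (adjusted p = 0.782). Of 27 Wnt pathway and leading domain genes, 14 rose and 6 fell, or 16 and 7 adjusted over the list alone. The rises included the Wnt feedback genes notum1a and notum1b (2.28) and lef1, a transcription factor of the Wnt pathway (1.52). The falls included tcf7l2 (-2.09), also a transcription factor of the pathway, and dkk2, which encodes a secreted modulator of Wnt receptors (-2.81). The list's median was 0.33 (camera adjusted p = 1.71e-05), and adjusted p = 0.166 with an estimated correlation. Of 28 Notch pathway genes, 10 fell and none rose, or 11 and 1 adjusted over the list alone, with a median of -0.18 (camera adjusted p = 2.08e-05, and adjusted p = 0.132 with an estimated correlation). They included the ligand genes jag2a (-1.80), dlb (-1.44) and dlc (-0.87) and the glycosyltransferase gene mfng (-1.51). Among 27 BMP and TGF-beta pathway genes 3 rose and 2 fell, or 6 and 3 adjusted over the list alone. The receptor gene bmpr1ba (1.16) and the ligand gene bmp4 (0.94) rose, and the ligand gene bmp2a fell (-1.20). That list's median was -0.09, its mean 0.03, and its test pointed up without passing (adjusted p = 0.959). Of 23 immediate early genes 2 rose, myca (1.44) and fosl2 (0.57), and klf2a fell (-0.86). Adjusted over the list alone the counts were 5 and 1, with a median of 0.09 (adjusted p = 0.147).

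Of 24 hair cell lineage genes 8 fell and 1 rose under SU5402, or 13 and 1 adjusted over the list alone. The transcription factor genes atoh1a (-1.42, SE 0.14), which hair cell formation requires, six2b (-2.60, SE 0.12) and insm1b (-1.18, SE 0.12) fell, as did the calcium-binding protein gene pvalb8 (-0.93, SE 0.09). The median was -0.34 (camera adjusted p = 9.30e-08), and adjusted p = 0.132 with an estimated correlation. Lateral line primordium identity genes went both ways, with 8 of 26 higher and 7 lower by either adjustment, over all probe sets or adjusted over the list alone (median 0.15, adjusted p = 0.266). The transcription factor genes dlx4b (2.04) and lef1 rose, and the chemokine decoy receptor genes ackr3b (-1.72) and ackr3a (-1.52) fell. Of 31 epithelial polarity, junction and apical constriction genes 13 fell and 1 rose, or 17 and 2 adjusted over the list alone. The tight junction genes oclna (-0.64) and marveld2b (-0.76), the non-muscle myosin gene myh9a (-0.72) and the angiomotin family gene amotl2a (-0.53) fell. The median was -0.22 (camera adjusted p = 2.08e-05), and adjusted p = 0.132 with an estimated correlation. The mean of the skin and periderm markers, which are epithelial too, was 0.71 lower on the same arrays (log2 difference -0.71). Among 26 basement membrane and matrix genes 7 rose and 4 fell, or 8 and 6 adjusted over the list alone. The integrin gene itga6b rose (0.91), and itga3b (-0.93), the laminin gene lamb4 (-1.03) and agrn (-0.48) fell (list median -0.06, adjusted p = 0.964).

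Cell cycle genes fell as a list, by a median of -0.75, with 27 of 32 lower and none higher, or 30 and none adjusted over the list alone. The call held with an estimated correlation (camera adjusted p = 2.73e-29, and adjusted p = 0.00575 with an estimated correlation), the single list of this comparison of which that was true. MKI67, a marker of cycling cells (-1.09, SE 0.08), the spindle checkpoint kinase gene ttk (-0.96, SE 0.07), the ribonucleotide reductase gene rrm1 (-1.05, SE 0.09) and the replication clamp gene pcna (-0.75, SE 0.07) were among them. Ribosome biogenesis and MYC target genes went the other way, with 23 of 30 higher and none lower, or 28 and none adjusted over the list alone. Their median was 0.42 (camera adjusted p = 4.56e-17), and adjusted p = 0.132 with an estimated correlation. Examples were mybbp1a (0.91), wdr43 (0.59), nop2 (0.57) and the nucleolar methyltransferase gene fbl (0.58).

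The remaining pathway lists did not pass as lists under SU5402. Among 21 p53 target and apoptosis genes 3 rose, with rps27l at 0.73, and 3 fell, with tp53inp1 at -0.55. Adjusted over the list alone the counts were 6 and 3 (median 0.13, adjusted p = 0.225). The other probe set of tp53inp1 did not pass. None of 17 heat shock genes passed by either adjustment, adjusted over the list alone included (median 0.10, adjusted p = 0.266). Of 25 unfolded protein response genes 5 fell, creld2 (-0.78) among them, or 6 adjusted over the list alone (median -0.09, adjusted p = 0.0971). Among 24 aryl hydrocarbon receptor and xenobiotic response genes 3 rose, with hmox1a, which encodes heme oxygenase, at 0.63, and 4 fell, with nfe2l2a at -0.79, or 3 and 5 adjusted over the list alone. That list's median was 0.02, its mean -0.02, and its test pointed down without passing (adjusted p = 0.972). Of 34 glycolysis and hypoxia genes pfkpb (-0.91) and gapdhs (-0.53) fell, and adjusted over the list alone the count was 2 as well. The median was 0.01, the mean -0.06, and the test pointed down without passing (adjusted p = 0.687). Of 22 sterol biosynthesis genes idi1 (0.44) and hsd17b7 (0.41) rose, again 2 adjusted over the list alone (median 0.04, adjusted p = 0.225). The call for hsd17b7 was lost when only the compared arrays were fitted (adjusted p = 0.101) and after a shift of array medians (adjusted p = 0.0772), and its other probe set did not pass. Among 19 steroid and glucocorticoid receptor response genes 3 rose and 1 fell, or 3 and 2 adjusted over the list alone (median 0.03, adjusted p = 0.548). The cortisol-inactivating enzyme gene hsd11b2 rose (2.30) and the mineralocorticoid receptor gene nr3c2 fell (-0.82).

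Markers of other cell types moved in both directions under SU5402, where 14.7% of all named genes passed. Of 28 skin and periderm markers 13 fell and 1 rose, or 17 and 1 adjusted over the list alone, with a median of -0.56 (camera adjusted p = 1.87e-10, and adjusted p = 0.132 with an estimated correlation). The desmosomal gene pkp1b (-2.30, SE 0.12), the hemidesmosomal collagen gene col17a1b (-1.90, SE 0.16), the keratin gene krt92 (-1.46, SE 0.12) and icn (-0.97, SE 0.12) fell, whereas the abundant skin markers krt4 (-0.19, adjusted p = 0.214) and cyt1l (-0.24, adjusted p = 0.189) did not pass. Of 19 endothelium markers 7 fell, with egfl7 at -1.71 and kdrl at -0.96, and 1 rose, or 10 and 1 adjusted over the list alone (median -0.31, camera adjusted p = 0.000141, and adjusted p = 0.132 with an estimated correlation). Of 14 ionocyte markers foxi3a fell (-1.15), or 4 adjusted over the list alone (median -0.48, camera adjusted p = 0.00578, and adjusted p = 0.473 with an estimated correlation). Of 22 neuron and glia markers syt1a (-0.53) and elavl4 (-0.68) fell, or 5 adjusted over the list alone (median -0.29, camera adjusted p = 0.00907, and adjusted p = 0.50 with an estimated correlation). Of 13 erythroid markers 3 rose, with the globin genes hbae3 at 1.06 and hbbe2 at 0.92, or 6 adjusted over the list alone (median 0.36, camera adjusted p = 0.00147, and adjusted p = 0.312 with an estimated correlation). The calls for syt1a, elavl4, hbae3 and hbbe2 were lost when only the compared arrays were fitted (adjusted p = 0.0532, 0.0882, 0.0564 and 0.0697). None of 27 skeletal muscle markers passed, adjusted over the list alone included, although the list did (median -0.19, camera adjusted p = 0.0265, and adjusted p = 0.817 with an estimated correlation). Of 22 leukocyte markers 3 fell, the lysozyme gene lyz (-2.19) among them, and 1 rose, or 5 and 1 adjusted over the list alone (median -0.11, adjusted p = 0.147). Among 20 neural crest and pigment cell markers 3 rose, with ednrba at 0.65, and 1 fell, or 3 and 3 adjusted over the list alone. That list's median was -0.09 and its mean -0.02, whereas its test pointed up without passing (adjusted p = 0.964). Of 25 mesenchyme and cartilage markers 2 fell, with the collagen gene col1a1a at -0.93, and 1 rose, or 3 and 1 adjusted over the list alone (median -0.10, adjusted p = 0.225). None of 18 pronephros markers passed, adjusted over the list alone included (median 0.02, mean -0.01, test pointing down without passing, adjusted p = 0.782).

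Under FGF overexpression 9 of 19 FGF-ERK feedback and target genes rose and none fell (camera adjusted p = 3.49e-10, and adjusted p = 0.0379 with an estimated correlation). Apart from fgf3, the largest measured rise was 21.8-fold for sost, a secreted antagonist of Wnt signalling (log2 change 4.44, SE 0.13, adjusted p = 2.85e-13, n = 6 per group). The ERK phosphatase gene dusp6 rose 2.59-fold (log2 change 1.37, SE 0.11, adjusted p = 3.15e-07). The largest measured fall was 4.96-fold for the T-box transcription factor gene tbx1 (log2 change -2.31, SE 0.14, adjusted p = 1.01e-08). Skin and periderm markers went both ways, with 1 of 28 higher and 2 lower.

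In the limma test 3052 of 75212 probe sets passed (4.06%), 1707 higher and 1345 lower. By the 1 probe set per gene, 1135 named genes passed, 657 higher and 478 lower, of which 175 changed by at least 2-fold, 109 up and 66 down. After fgf3 and sost, the measured rises were largest for hspa8b, of the heat shock protein 70 family (3.42, SE 0.26, a lower bound), oc90, which encodes an otoconial protein (3.26, SE 0.18), sostdc1a (3.23, SE 0.16), the chemokine decoy receptor gene ackr3a (3.03, SE 0.18), dkk2 (2.82, SE 0.15) and the homeobox gene gbx2 (2.38, SE 0.18). The place of hspa8b in this order is not settled. The other, dimmer probe set of oc90 rose by 1.25 (limma adjusted p = 0.000188). After tbx1, the falls were largest for the histone gene hist1h2a11 (-2.31, SE 0.35), the Wnt modulator gene sfrp2 (-2.02, SE 0.17), the atypical cadherin gene fat1b (-2.0, SE 0.11), ggact.3 (-1.97, SE 0.11, a lower bound in size), the protocadherin gene pcdh12 (-1.91, SE 0.13), the ligand gene wnt2 (-1.87, SE 0.13) and cyp26a1, which encodes an enzyme that breaks down retinoic acid (-1.87, SE 0.13). Adjusted p-values of these 16 genes ranged from 2.85e-13 for sost to 0.000359 for hist1h2a11.

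Of 19 FGF-ERK feedback and target genes 9 rose and none fell, or 12 and none adjusted over the list alone. The median was 0.42, and the call held with an estimated correlation (camera adjusted p = 3.49e-10, and adjusted p = 0.0379 with an estimated correlation), the single list of this comparison of which that was true. The rises were etv4 (1.73, SE 0.14), dusp6, spry4 (1.26, SE 0.15), spry1 (1.02), spred2b (0.91), spred2a (0.76), spry2 (0.72), dusp4 (0.53) and etv5a (0.44). Values for those that did not pass were 0.42 for etv5b (adjusted p = 0.108), 0.28 for spred1, 0.24 for il17rd, -0.22 for flrt3, -0.19 for spred3, 0.16 for dusp5, 0.16 for cdc42ep3, 0.06 for dusp1, 0.06 for etv1 and 0.01 for dusp2. With array weights etv5b and spred1 passed (adjusted p = 0.0388 and 0.0297), and with a trended and robust variance spred1 and il17rd did (adjusted p = 0.033 and 0.0358). Among 19 FGF ligands and receptors 2 rose and 4 fell, or 4 and 4 adjusted over the list alone. The ligand genes fgf10a (-1.55) and fgf10b (-1.33) and the receptor gene fgfr1b (-0.72) fell. The list's median was -0.11 and its mean 0.12, opposite in sign, and its test pointed down without passing (adjusted p = 0.509).

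Of 27 Wnt pathway and leading domain genes 10 fell and 4 rose under FGF overexpression, or 12 and 5 adjusted over the list alone. The Wnt modulator gene sfrp1a (-1.27) and lef1 (-1.39) fell, and dkk2 and the receptor gene fzd8a (1.66) rose. The median was -0.17 (camera adjusted p = 0.00412), and adjusted p = 0.597 with an estimated correlation. Of 28 Notch pathway genes 5 rose, with mfng at 1.08 and dlb at 1.08, and 3 fell, with notch2 at -0.53 and jag1b at -0.59. Adjusted over the list alone the counts were 6 and 3 (median 0.10, adjusted p = 0.255). Of 27 BMP and TGF-beta pathway genes 5 rose and none fell, or 6 and none adjusted over the list alone (median 0.08, adjusted p = 0.0584). They included the ligand gene bmp2a (1.07) and the BMP-induced gene id2a (0.47). Of 23 immediate early genes myca fell (-0.58) and none rose, or 6 and 1 adjusted over the list alone (median -0.04, adjusted p = 0.255).

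Of 24 hair cell lineage genes 3 rose and 1 fell, the same counts as when adjusted over the list alone. Those 4 were pvalb8 (0.87), the otoferlin gene otofa (0.71) and insm1b (0.47), which rose, and pvalb9, which fell (-0.87). The median was 0.16 (camera adjusted p = 0.00412), and adjusted p = 0.597 with an estimated correlation. The call for insm1b was lost when only the compared arrays were fitted (adjusted p = 0.0551). Among 26 lateral line primordium identity genes 4 rose, with ackr3a and sox3 (1.08) the clearest, and 4 fell, with lef1 and fgf10a the clearest, or 5 and 6 adjusted over the list alone (median 0.05, adjusted p = 0.806). Of 31 epithelial polarity, junction and apical constriction genes 4 fell, including amotl2b (-1.18), and the polarity gene llgl2 rose (0.39), or 6 and 5 adjusted over the list alone (median -0.04, adjusted p = 0.650). Among 26 basement membrane and matrix genes 2 rose, with itga5 at 1.34, and 4 fell, with itga3b at -0.97 and itga6b at -0.70, or 4 and 4 adjusted over the list alone. That list's median was 0.01, its mean -0.04, and its test pointed down without passing (adjusted p = 0.942).

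Of 32 cell cycle genes 4 fell under FGF overexpression, MKI67 (-0.40) and the mitotic kinase gene aurkb (-0.44) among them, and none rose, or 5 and none adjusted over the list alone. The median was -0.15 (camera adjusted p = 0.00104), and adjusted p = 0.597 with an estimated correlation. Of 30 ribosome biogenesis and MYC target genes 5 fell, with mybbp1a at -0.71, npm1a at -0.53 and bop1 at -0.38, and none rose, or 13 and none adjusted over the list alone. The median was -0.22 (camera adjusted p = 2.84e-08), and adjusted p = 0.597 with an estimated correlation. Of 24 aryl hydrocarbon receptor and xenobiotic response genes 3 rose, including the cystine transporter gene slc7a11 (1.15), and none fell, or 6 and 1 adjusted over the list alone. The median was 0.09 (camera adjusted p = 0.0241), and adjusted p = 0.508 with an estimated correlation. The probe set of slc7a11 was dim, with a mean of 4.16 over the 18 arrays against a median level of 5.91 in control. Its change is a lower bound in size. Among 21 p53 target and apoptosis genes 2 rose, with baxb at 0.52, and 1 fell, or 3 and 4 adjusted over the list alone (median 0.05, adjusted p = 0.806). Of 17 heat shock genes hspa8b rose, and adjusted over the list alone it was again 1. That list's median was -0.06 and its mean 0.14, opposite in sign, and its test pointed down without passing (adjusted p = 0.806). Of 25 unfolded protein response genes atf6 rose (0.27), or 2 adjusted over the list alone (median 0.02, adjusted p = 0.513). Of 34 glycolysis and hypoxia genes pgam1b rose (0.35), or none adjusted over the list alone (median -0.07, adjusted p = 0.728). The calls for atf6 and pgam1b were lost when only the compared arrays were fitted (adjusted p = 0.0759 and 0.0732), and that for pgam1b also after a shift of array medians (adjusted p = 0.0546). None of 22 sterol biosynthesis genes passed, adjusted over the list alone included (median 0.11, adjusted p = 0.258). Among 19 steroid and glucocorticoid receptor response genes 2 rose, with nr3c2 at 1.45, and hsd11b2 fell (-0.90), with 2 and 1 adjusted over the list alone (median 0.02, adjusted p = 0.806).

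Some markers of other cell types changed under FGF overexpression, where 5.89% of all named genes passed. Of 28 skin and periderm markers the fin fold gene and2 rose (0.94), and the collagen genes col17a1b (-1.28) and COL7A1 (-0.53) fell, or 1 and 3 adjusted over the list alone (median -0.10, adjusted p = 0.255). Of 22 leukocyte markers 3 rose, the matrix metalloproteinase gene mmp9 (1.24) among them, and again 3 adjusted over the list alone (median 0.02, adjusted p = 0.161). Of 19 endothelium markers 3 rose, with egfl7 at 1.25, and kdrl fell (-0.92), the same counts as when adjusted over the list alone (median -0.13, adjusted p = 0.708). Of 20 neural crest and pigment cell markers sox10 rose (0.66) and tfap2a fell (-0.67), also 1 and 1 adjusted over the list alone (median -0.15, adjusted p = 0.313). Of 22 neuron and glia markers snap25b rose (0.50), and adjusted over the list alone it was again 1. That list's median was -0.03 and its mean 0.06, opposite in sign, and its test pointed up without passing (adjusted p = 0.728). The call for snap25b was lost when only the compared arrays were fitted (adjusted p = 0.0523). None of 27 skeletal muscle markers and none of 25 mesenchyme and cartilage markers passed, adjusted over the list alone included. The medians were -0.24 for muscle (camera adjusted p = 0.00750, and adjusted p = 0.931 with an estimated correlation) and -0.32 for mesenchyme and cartilage (camera adjusted p = 0.0108, and adjusted p = 0.931 with an estimated correlation). None of the 14 ionocyte markers (median 0.04, mean -0.02, test pointing down without passing, adjusted p = 0.855), 18 pronephros markers (median -0.20, adjusted p = 0.185) or 13 erythroid markers (median 0.10, adjusted p = 0.650) passed, adjusted over the list alone included.

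**Figure D3:**
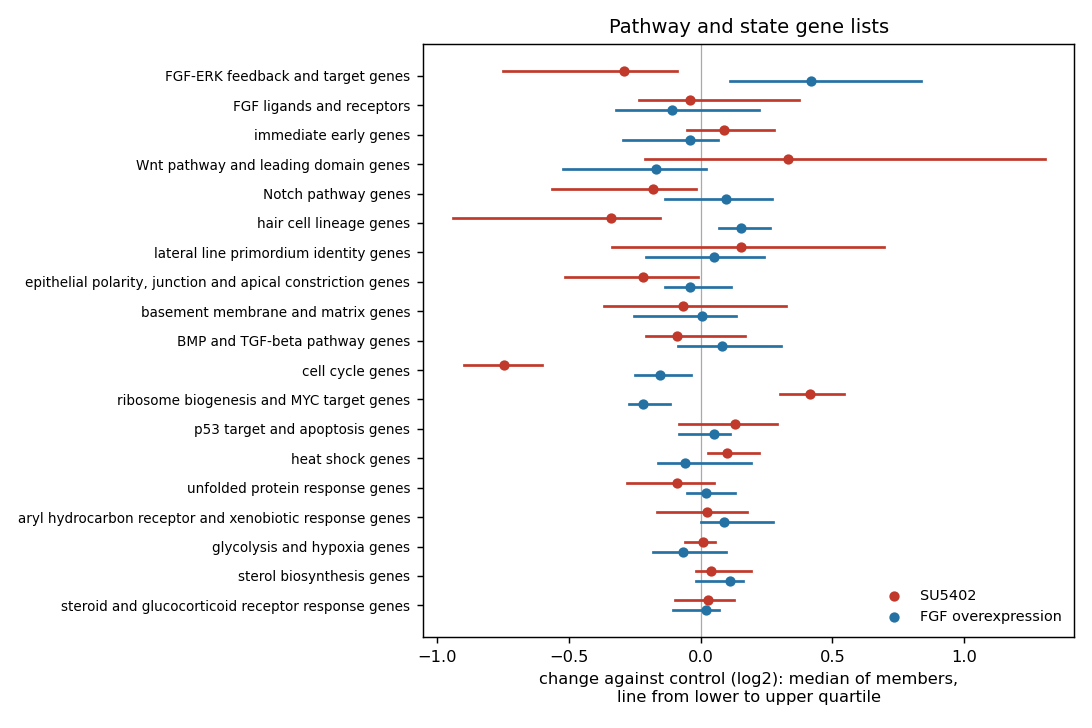
Change against control (log2, horizontal) of the 19 pathway and state gene lists (vertical) under SU5402 and FGF overexpression, with a point at the median of the members and a line from the lower to the upper quartile. FGF-ERK feedback and target genes lie at -0.29 and 0.42, ribosome biogenesis genes at 0.42 and -0.22, and cell cycle genes at -0.75 and -0.15.

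Between the overexpression and inhibitor arms, the FGF target gene etv4 and the Wnt modulator genes dkk2 and sost were higher under FGF overexpression, and the Wnt feedback gene notum1a and the ligand gene fgf10b were higher under SU5402. Differences upward were largest for 5 genes, of which the first 4 have no settled order because SU5402 was at or below the median level. They were at least 67.6-fold for negaly6 (log2 difference 6.08, SE 0.16, adjusted p = 9.05e-15, n = 6 per group), at least 49.5-fold for dkk2 (5.63, SE 0.15), at least 38.1-fold for etv4 (5.25, SE 0.14), at least 34.4-fold for b3galt10.1 (5.10, SE 0.24) and 33.8-fold for sost (5.08, SE 0.13). The largest differences downward were for adcyap1b (-4.75, SE 0.14), notum1a (-4.44, SE 0.15), hbegfb (-4.03, SE 0.13), runx2a (-3.97, SE 0.14) and fgf10b (-3.73, SE 0.15), where adcyap1b and fgf10b are lower bounds in size. The difference for fgf3 was 3.28 (SE 0.17) and for dusp6 1.34 (SE 0.11). In the limma test 12731 probe sets passed (16.9%), 5929 higher under FGF overexpression and 6802 lower. The balance turned with the scaling, with 6609 of 12642 higher after repeated quantile normalization and 6946 of 12312 after a shift of array medians. By the 1 probe set per gene, 4697 named genes passed, 2407 higher and 2290 lower, of which 806 differed by at least 2-fold, 506 up and 300 down.

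Of 19 FGF-ERK feedback and target genes 11 were higher under FGF overexpression than under SU5402 and 1 lower, the same counts as when adjusted over the list alone (median 0.82, camera adjusted p = 2.70e-08, and adjusted p = 0.0513 with an estimated correlation). Of 24 hair cell lineage genes 13 were higher and none lower, or 17 and none adjusted over the list alone (camera adjusted p = 2.76e-08, and adjusted p = 0.140 with an estimated correlation). Of 32 cell cycle genes 27 were higher and none lower, or 28 and none adjusted over the list alone (camera adjusted p = 1.39e-16, and adjusted p = 0.0513 with an estimated correlation). Of 30 ribosome biogenesis and MYC target genes 28 were lower and none higher, or 30 and none adjusted over the list alone (camera adjusted p = 2.93e-19, and adjusted p = 0.108 with an estimated correlation). Of 27 Wnt pathway and leading domain genes 16 were lower and 6 higher, or 17 and 7 adjusted over the list alone (camera adjusted p = 6.95e-06, and adjusted p = 0.217 with an estimated correlation). Of 28 skin and periderm markers 11 were higher and 1 lower, or 16 and 1 adjusted over the list alone (camera adjusted p = 5.14e-06, and adjusted p = 0.373 with an estimated correlation). In all, 13 of the 29 lists passed in this comparison, and with an estimated correlation the number was 0.

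Of the 511 genes that passed in both comparisons with control, 374 (73.2%) moved in opposite directions. Genes that fell under SU5402 and rose under FGF overexpression included dkk2 (-2.81 and 2.82), the orphan nuclear receptor gene rorb (-1.84 and 1.83), the cell adhesion gene esama (-1.80 and 2.0), b3galt10.1 (-3.35 and 1.76), etv4 (-3.53 and 1.73), the glycosyltransferase gene mgat1b (-1.75 and 1.61) and ackr3a (-1.52 and 3.03). The reverse held for fgf10a (1.56 and -1.55), the secretory kinase family gene fam20cb (1.44 and -1.58) and lef1 (1.52 and -1.39). There were 236 genes lower under SU5402 and higher under FGF overexpression, where independent calls would give 53.4, and 138 the other way, where they would give 31.4. Genes higher in both numbered 31 (43.2 if independent), fgf3 among them, and genes lower in both 106 (38.9 if independent), with tbx1 at -1.57 and -2.31.

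**Figure D4:**
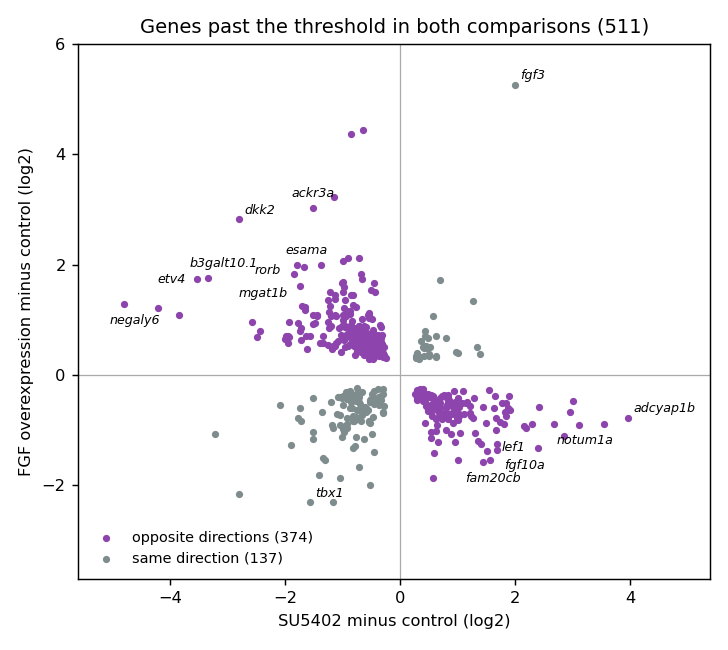
Log2 change under SU5402 (horizontal) and under FGF overexpression (vertical), both against control, of the 511 genes past the threshold in both comparisons, 1 point per gene. The 374 genes with opposite directions lie in the upper left and lower right parts, and fgf3 lies at the upper right at 1.99 and 5.26.

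Because both comparisons use the same 6 control arrays, their effects share error that pushes them the same way. Over all probe sets, the covariance of the log2 changes was 0.00371. In 100 simulated pairs of unchanged groups against the same controls it averaged 0.0192 and ranged from 0.00401 to 0.0315, so the observed value lay below the lowest simulated one (difference from the simulated mean -0.0155). The correlation of the changes across probe sets, which are not independent replicates, was 0.0394, against a simulated mean of 0.517 (range 0.190 to 0.717). Effects of opposite sign made up 43.4% of probe sets, against a simulated mean of 32.7% and a highest simulated value of 44.6%. The simulated groups held no treatment effects. Real effects that are unrelated between the treatments would also lower the correlation and raise the share of opposite signs. Neither the correlation nor that share can therefore show that the treatments oppose each other. With different controls for each treatment, 3 and 3 in all 20 ways, the covariance averaged -0.0135 and the correlation -0.121. That setting did not pass against its simulations (difference -0.0139, 0.03 of them at or below). Each simulated value used 1 split of the controls, whereas the observed one was a mean over 20. Their spreads are therefore unlike, and this setting cannot decide. The fits without control replicate 1 (difference -0.00926, 0.1 at or below) and control replicate 4 (difference -0.0117, 0.04 at or below) did not pass either. The threshold for this relation, a two-sided share of 0.05, was set after the simulated values had been seen. The comparison of each setting with its own simulations was also chosen late, after a first version on the covariance itself, whose sign changed with split controls (-0.0135) and with dim probe sets left out (-0.0114), had been seen.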

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

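The 5 tests of explanations for skin markers, fgf3 and hspa8b were chosen after the result was seen, and the counts over other splits of the arrays were planned beforehand.

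Of 100 drawn splits of the 12 control and SU5402 arrays into groups of 6, out of 462 possible, 1 gave as many changed probe sets as the real split, namely the real split itself (7074, highest other 147). For FGF overexpression and control it was again 1 of 100 (3052, highest other 74), and for FGF overexpression and SU5402 also 1 of 100 (12731, highest other 7). Chance division of the arrays can be excluded for these 3 counts.

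In 35 of 525 groups tested (175 levels in 3 groups of 6), 1 array stood apart from the other 5. Chance alone gives about 1 in 20 such groups. The number after each name is the array's gap to its nearest neighbour divided by the range of the group. In control, replicate 1 was lowest for and2 (0.811), the mean of the skin and periderm list (0.732), cyt1l (0.731) and krt4 (0.714), and highest for sema3fa (0.707) and dusp1 (0.647). Control replicate 5 was lowest for fut9b.3 (0.710), cxcr4b (0.688), sema4ba (0.659) and fgf10a (0.632), and highest for sost (0.667). Also in control, replicate 2 was lowest for lyz (0.797), replicate 3 highest for insm1b (0.628), replicate 4 highest for oc90 (0.633), and replicate 6 highest for the means of the endothelium list (0.717) and of the neural crest and pigment cells list (0.640).

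In the SU5402 group, replicate 6 was highest for col1a1a (0.726) and ackr3a (0.686), replicate 2 lowest for lyz (0.684), and replicate 5 lowest for spred3 (0.673) and highest for cyp26a1 (0.641) and fat1b (0.629). Replicate 4 was highest for llgl2 (0.654) and replicate 1 highest for dusp2 (0.637). In the FGF overexpression group, replicate 1 was lowest for sema3fa (0.927, with a level of 6.39 against a mean of 7.05 on the other 5), hbae3 (0.658), wdr43 (0.641) and hbbe2 (0.631). Replicate 5 was lowest for ackr3b (0.667) and negaly6 (0.635) and highest for syt1a (0.675). Replicate 3 was highest for nop2 (0.689), replicate 2 highest for bmp2a (0.654), and replicate 6 highest for sfrp2 (0.644) and aurkb (0.630).

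Skin and periderm markers were lower in SU5402, by -0.71 in the mean of the list (exact permutation p = 0.00433, two-sided, adjusted p = 0.0144 over the 10 lists of other cell types, n = 6), against -0.05 in FGF overexpression. A lower share of all other cell types would lower the 10 lists alike. The mean of the other 9 lists changed by -0.15 (exact permutation p = 0.193). Among them endothelium was at -0.43 and leukocytes at -0.22 (adjusted p = 0.0108 each), and erythroid cells at 0.51 (adjusted p = 0.054, not passed). The skin list fell further than the mean of these 9 by -0.56 (exact permutation p = 0.00216). It was flagged for its fall, so that p-value is no independent evidence against a shared fall. Fewer skin and periderm cells may remain: the 7 members with the highest control level had a median of -0.61 against -0.56 for the list, and 4 of the 7 passed as lower. Fewer such cells cannot be told apart from lower transcription of these genes in the sampled cells, because either would lower the level of these members. As a further limit, 3 of the 7, krt91, krt4 and cyt1l, lie at 12.18, 12.09 and 12.06 in control. These levels are within 2 log2 units of the highest array value of 13.88, where an array can compress changes. Of the 28 measured members 2 are also on another list, the number that the primordium itself expresses is not known from these data, no sort that would remove skin cells is stated, and a biological effect of SU5402 on these genes remains untested.

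The ligand gene fgf3 was higher in SU5402 than in control, by 1.99 (SE 0.17). RNA from the FGF overexpression group on the SU5402 arrays would raise the other genes with the largest rise under FGF overexpression. These other 7 of the 8 had a mean change of -1.02 (exact permutation p = 0.00216, two-sided, n = 6), with 7 below 0, 4 passing as lower and 0 as higher. They were picked for their rise under Fgf3, so the inhibitor could lower them with or without such RNA. The test therefore cannot decide, and its p-value does not measure such RNA. An effect of the inhibitor on the native fgf3 gene may explain the rise and remains untested.

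The heat shock family gene hspa8b rose by 3.42 under FGF overexpression, and si:dkey-4p15.5, its neighbour among the measured named genes on chromosome 15, chosen after its values were seen, by 4.36 (SE 0.20, adjusted p = 1.91e-10). Under SU5402 they were at -0.17 (adjusted p = 0.787) and -0.85 (adjusted p = 0.00980). A heat shock response was argued against, since the other 16 heat shock genes had a median of -0.07, a range from -0.75 to 0.83 and 0 that rose. A local difference in genotype beside the gene, linked to the transgenes or the strain, may be a candidate explanation and cannot be told apart from an effect of Fgf3, because only the FGF overexpression group carries the extra transgenes. Of the 20 flanking named genes 3 changed, where 1.17 would be expected (exact hypergeometric p = 0.108). Under SU5402, in embryos with the control genotype, all 3 passed in the other direction. They were si:ch211-229d2.5 (1.22 under FGF overexpression and -4.22 under SU5402), arhgap32a (0.71 and -1.57) and thyn1 (-0.43 and 0.82). The count therefore does not speak for a local difference in genotype.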

How the results depend on the processing

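Identical sets of values counted once, the muscle covariate and the test of muscle means within replicate numbers were chosen after seeing the data, and the other alternatives were planned. The number of changed probe sets stayed within 1.5 times the reported one under most alternatives. Over the replicate block, the fit of 2 groups only, trended and robust variance, array weights, repeated quantile normalization, a shift of array medians and the filter on dim probe sets, it ran from 5955 to 8390 for SU5402, from 2817 to 3950 for FGF overexpression and from 11498 to 14287 for FGF overexpression against SU5402. Among settings that keep all probe sets, those with an array left out aside, 80.3% to 98.7% of the reported calls for SU5402, 82.2% to 99.1% for FGF overexpression and 88.7% to 98.6% for the third comparison were kept. With each array left out in turn the counts ran from 5998 to 7178, from 2427 to 3193 and from 11182 to 13220, and the calls kept from 81.7% to 96.7%, from 75.9% to 96.9% and from 84.3% to 98.4%. Scaling moved the balance of higher and lower calls. After repeated quantile normalization and after a shift of array medians, 3090 of 7024 and 2765 of 6787 were higher for SU5402 (3526 of 7074 as reported), and 6609 of 12642 and 6946 of 12312 in the third comparison, where the majority turned (5929 of 12731 as reported). Identical sets of values counted once gave 6704, 3020 and 11960, and the muscle covariate 6707, 2900 and 13504. Counting 1 probe set per gene gave 3270, 1311 and 5142 changed, and a fold of at least 1.5 gave 3574, 1704 and 6318, where fewer tests and a stricter threshold lower the count by construction. With an estimated correlation the lists that passed fell from 13 to 1 for SU5402, from 8 to 1 for FGF overexpression and from 13 to 0 between them. The estimates ran from -0.002 for leukocytes to 0.912 for skeletal muscle, and why each list lost its call was not tested. By fry, which tests a list on its own, 16, 6 and 20 passed against 13, 8 and 13. The fgf3 change ran from 1.82 to 2.08, from 5.10 to 5.36 and from 3.2 to 3.34 with each array left out, and the median of the FGF-ERK genes from -0.37 to -0.25, from 0.36 to 0.47 and from 0.74 to 0.90. The covariance of the SU5402 and FGF overexpression effects, as the difference from its own simulations, was -0.0155. It did not pass with controls split 3 and 3 (-0.0139). There a mean over 20 splits was set against simulations of 1 split each, so that setting cannot decide. With each array left out the difference ran from -0.0180 to -0.00926, and the values without control replicate 1 (-0.00926) and control replicate 4 (-0.0117) did not pass. The cause was not tested. No named gene that passed reversed under the 6 alternatives run for single genes, and no list that passed under the 4 run for lists. The replicate block, the fit of 2 groups only and the trended and robust variance leave the group differences unchanged. Only array weights, repeated quantile normalization and the shift of medians could therefore reverse a gene. For lists, the setting with an estimated correlation was given the direction of the main test and could not reverse. Single genes other than fgf3 were not refitted with an array left out, the dim filter or the muscle covariate. The covariance itself, on which a first version of the relation was judged, changed from 0.00371 to -0.0135 with split controls and to -0.0114 with dim probe sets left out, and its difference from simulations was chosen after that had been seen. Of the single genes tested under the alternatives, 1402 results stayed on their side of the threshold, 15 fell below it and 11 passed it. The replicate numbers missed the rule set for pairing, that each pair of arrays with the same number has a correlation of residuals over 0.1. Of 18 such pairs 8 did (range 0.012 to 0.226, median 0.087 against -0.022 for other pairs). The best match of an array among the 6 arrays of another group bore the same number in 20 of 36 cases. These values, with the muscle means given further below, point to something shared by arrays with the same number, which the reported tests leave out. With the numbers as a replicate block, 8390, 3950 and 14287 probe sets passed. Under FGF overexpression insm1b (adjusted p = 0.0591) and pgam1b (adjusted p = 0.0644) then did not pass, and spred1 (adjusted p = 0.0381), wnt7aa (adjusted p = 0.042) and the BMP and TGF-beta list (adjusted p = 0.0437) did, as did cdc42ep3 under SU5402 (adjusted p = 0.0474) and the immediate early and unfolded protein response lists between the 2 treatments (adjusted p = 0.0263 and 0.0413). The muscle marker mean differed from control by -0.23 for SU5402 and -0.27 for FGF overexpression (exact permutation p = 0.303 and 0.149), and within replicate numbers it was lower in 6 of 6 for each (exact p over sign changes = 0.0312 for both). Signal over background limits dim probe sets: the median level was 5.52 for unnamed and 6.82 for named ones.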

Other observations

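The values of neighbouring genes and of the muscle markers below were looked at after the result was seen, and the tests of gene families were set before their results were seen.

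Sorted by the letters of their symbols, 336 families of at least 8 measured genes were tested for an excess of changed genes, and some symbol families changed more often than other genes. In SU5402 the number of families was 2, Wnt ligands and semaphorins. Of 23 wnt genes 12 changed, 6 up and 6 down, where 3.38 would be expected (hypergeometric adjusted p = 0.00507), and of 30 semaphorin genes, which encode guidance cues, 14 changed, 9 up and 5 down (4.41 expected, adjusted p = 0.00507). Under FGF overexpression the number was 3. Of the semaphorin genes 11 changed, 4 up and 7 down (1.77 expected, adjusted p = 0.000184), of the wnt genes 8, 2 up and 6 down (1.36 expected, adjusted p = 0.00527), and of 13 hoxc genes 6, all of them down (0.766 expected, adjusted p = 0.00555). Genes of 1 family can share probe sequence or a chromosome neighbourhood, so that they are not independent in this test.

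The members below were chosen after their values were seen. The 6 hoxc genes that fell under FGF overexpression all rose under SU5402, though the family did not pass there (6 of 13, adjusted p = 0.152). The changes under SU5402 and FGF overexpression were 1.66 and -1.0 for hoxc1a, 1.21 and -0.57 for hoxc8a, 1.03 and -0.74 for hoxc6a, 1.0 and -0.53 for hoxc4a, 0.99 and -0.51 for hoxc5a, and 0.59 and -0.47 for hoxc3a, the last of which missed the threshold under FGF overexpression when only the compared arrays were fitted (adjusted p = 0.0611). Opposite changes were seen, among others, for wnt3 (1.40 and -1.25), wnt6b (1.81 and -0.89), sema3fa (0.95 and -1.21), sema3gb (0.78 and -0.70) and sema4c (-0.84 and 0.97). The genes wnt9a (-0.97 and -1.04), wnt2 (-1.05 and -1.87) and sema5a (-0.55 and -0.84) fell in both. Under SU5402 alone of the comparisons with control, wnt7aa (-1.27) and sema4ba (1.67) passed, though wnt7aa also passed under FGF overexpression with array weights (adjusted p = 0.0412), and under FGF overexpression alone, sema3ga (1.99) and wnt11 (1.24). FGF overexpression and SU5402 differed in each of these 4 genes (adjusted p = 0.0105, 7.07e-12, 7.25e-11 and 0.000193).

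Neighbouring named genes changed the same way in 364 of 18777 pairs under SU5402, against a mean of 204 and a highest value of 247 in 1000 shuffles of the gene order, and in 91 pairs under FGF overexpression, against 32.5 and 53. The mean of the 27 skeletal muscle markers ran from 10.00 to 11.03 (log2) over the 18 arrays. Arrays with the same replicate number had more similar muscle means across the 3 groups than in any of 100000 permutations (permutation p = 1e-05, the smallest they can give).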
